A study of Homo sapiens with 12 samples.

How the data were processed

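The deposited table of single probes holds, per the file headers, a signal for each probe and array in intensity units, from which the authors had subtracted the background of each array and which they had not normalized between arrays. Beside each signal the deposited table gives a detection p-value, which compares the probe with negative control beads. A second deposited table holds values on the log2 scale that the authors had quantile normalized over the 12 arrays. BeadStudio, lumi and limma were used upstream, per the submitters' processing notes. All columns were matched to the 12 samples by their titles, and 0 columns were left unmatched. The genome build of the probes is not given in the sources used here, and gene lengths came from the RefSeq table of assembly GRCh38.p14.

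In the table of signals, 9 arrays had their values displaced by 1 position from probe 22924 on, which affected 24399 probes. Before realignment the Spearman correlation across probes between a displaced array and the authors' normalized values was 0.511 to 0.529, and after it was 1 on all 12 arrays. The last of the 47322 probes had no value on the displaced arrays after realignment and was left out. Of the 47321 analysed probes 30111 had 1 gene symbol, 8 had several and 17202 had none.

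The signals were processed with limma 3.58.1 in R 4.3.3. Background correction used neqc with the detection p-values and an offset of 16, followed by quantile normalization and log2. Probes with a detection p under 0.01 on at least 2 of the 12 arrays were kept, 19357 in number, of which 4529 had no symbol and were not tested. Each of the 11305 genes was represented by its probe with the highest mean, and 2841 genes had more than 1 kept probe. A model with 1 mean for each of the 6 groups was fitted to all 12 arrays (6 residual degrees of freedom), with eBayes and a two-sided moderated test, and p-values were adjusted by the Benjamini-Hochberg method for each comparison. The 3-line mean weighted the lines equally. Differences in response between lines were tested by a moderated F test and by pairwise contrasts.

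Where a group was not above background on either of its arrays, the fold was bounded by setting that group, on each array, to the lowest value of a detected probe or to its own value, whichever was higher, and no fold is given where the bound was under 1 or both groups were undetected. Errors are standard errors of the fitted difference.

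A set of 20 gene lists was tested with limma's camera (preset correlation 0.01, two-sided), adjusted over the 60 tests of 20 lists in 3 lines, and likewise within the 3-line mean and the pairwise differences. They were p53 targets, NRF2 targets, heat shock genes, ER chaperones and the unfolded protein response, ATF4 and amino acid response, the BCL2 family, metallothioneins and metal response, mitotic genes, DNA replication genes, MYC and ribosome biogenesis, immediate early genes, NF-kB targets, plasma cell identity, glutathione and thioredoxin systems, proteasome subunits, sterol synthesis, interferon response, autophagy and lysosome, markers of other cell types and housekeeping genes. The lists, the tests on them and on single genes, most alternatives and the rule for naming genes were fixed before the data were examined. Realignment, 4 alternatives and the tests of RNA classes were chosen after.

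Genes were named by that rule: in each line the 5 largest rises and 5 largest falls past an adjusted p of 0.05 whose treated arrays both lay beyond both control arrays, up to 2 members of each list with the largest change past the threshold, and 6 fixed genes whatever their result. For the 3-line mean the 5 largest rises and falls with one sign in all lines were named, and for each pairwise difference the 3 largest either way. The rule gave 124 genes, of which 122 were measured; 1 of the falls in the 3-line mean is not reported here.

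In a self-test, values for the 11305 genes were simulated from the control means and each gene's spread within groups, changes of known size were added in MM.1S for 200 genes, and the same model was fitted. It called 47.8% of 67 genes moved by 0.5 log2 units, 77.6% of 67 moved by 1 and 95.5% of 66 moved by 2, along with 9 genes that had not been moved, and no list other than the moved one was called. The simulation gave a gene the same spread in all groups, so it does not cover a group with noisier arrays.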

Results

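Gene expression was measured in 3 human multiple myeloma cell lines after 8 h with PRIMA-1Met or with DMSO, its solvent. PRIMA-1Met (APR-246) is a small molecule that is converted in cells to a thiol-binding product and is studied as a compound that restores function to mutant p53. The labels give MM.1S as p53 wild type, U266 as p53 mutant and 8226R5 as p53 null. MM.1S was treated at 20 µM and the other lines at 40 µM, so cell line, p53 status and dose cannot be told apart in this design. Total RNA was hybridised to 12 Illumina HumanHT-12 arrays in 6 groups, 2 treated and 2 control arrays for each line. The comparisons asked which genes changed with the drug in each line, how far the changes were shared, and where the lines differed. The labels do not say that the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Each gene had 1 spread, pooled over the 6 groups. Replicates differed more in treated MM.1S (SD of the difference 0.43 log2 units) than in the other groups (0.176 to 0.246). Errors and p-values may therefore be too small for MM.1S and too large for the other lines.

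Between 11815 and 16025 of the 47321 analysed probes were detected on an array (detection p under 0.01). The lowest numbers came from the treated MM.1S arrays, with 11815 and 12093 detected probes. In MM.1S the 90th percentile of signal was 812.5 intensity units in the controls and 213.7 in the treated arrays (means, n = 2). In U266 it was 905.3 and 535.4, and in 8226R5 it was 700.9 and 867.2. The 100 brightest probes held 17.6% of the signal in MM.1S controls and 27.7% after treatment. Replicate arrays correlated at r = 0.984 to 0.997 across genes, lowest in treated MM.1S. Arrays of one line but different treatment correlated at 0.867 to 0.989 and arrays of different lines at 0.719 to 0.844; genes are not independent replicates in these values. In all, 11305 genes were tested.

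**Figure D1:**
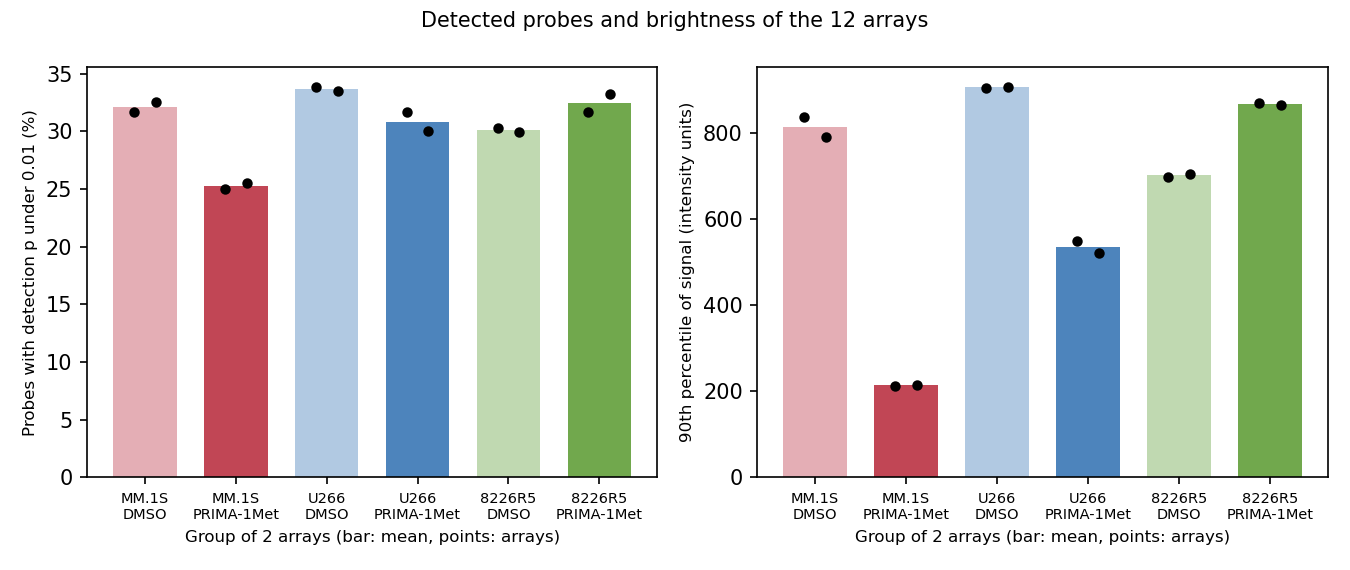
Percentage of probes with a detection p under 0.01 (left) and 90th percentile of probe signal in intensity units (right) for the 6 groups; bars are means and points are the 2 arrays of a group. The treated MM.1S arrays have the lowest values in both panels, with a mean of 25.3% of probes detected and a 90th percentile of 213.7.

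In MM.1S, immediate early genes rose relative to all genes, and the largest single rises included an inducible chaperone, a histone and a small nuclear RNA. HSPA6, a strictly inducible Hsp70 chaperone, was at least 98.7-fold higher after treatment (limma adjusted p = 3.21e-10, n = 2 per group). Another probe of HSPA6 gave 4.88 log2 units, a smaller change than that bound. HSPA1A, another inducible Hsp70, rose by 5.50 ± 0.13 on the log2 scale (SE). The replication-dependent histone transcript H4C1 was at least 51.0-fold higher, and the spliceosomal small nuclear RNA RNU4-2 rose by 6.65 ± 0.08 log2 units. The other members of the 5 largest fitted rises were the probes annotated to MIR425, at least 51.1-fold higher, and to LOC105274304, with a log2 change of 6.65 ± 0.09. The largest fitted falls, all against treated arrays not above background so that their bounds do not establish the rank, were those of JAK1, a kinase of cytokine receptors (at least 3.94-fold), GATAD2B, a subunit of the NuRD repressor complex (at least 4.14-fold), NREP (at least 3.33-fold), the non-coding transcript LINC00294 (at least 4.27-fold) and LARS2, the mitochondrial leucyl-tRNA synthetase (at least 2.49-fold), with limma adjusted p between 4.71e-09 and 9.73e-07. A value given as at least N-fold means that the dimmer group was not above background on either array. It is a bound for that probe on the main quantile-normalized values and not under every scaling. Over 5 ways of scaling and background handling, several of the smallest fitted changes were smaller in size than the bounds given here. In MM.1S they included -1.82 log2 units for LINC00294, 3.22 for FCGR3A and 3.97 for EGR1. In U266 they included 6.8 for MT1G and 4.4 for EGR1. Probes of close paralogs, such as the Hsp70, metallothionein and histone genes, may share signal.

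Of the 11305 genes, 8372 (74.1%) changed in MM.1S at a limma adjusted p under 0.05, 2709 up and 5663 down. A change of at least 2-fold, the criterion of the study's design without a test, was met by 4125 genes, 1448 up and 2677 down. The split depended on the scaling of the treated arrays, which were dim. The quantile-normalized values put the median change of all genes at -0.35 log2 units. Median scaling moved that median to -0.04 and gave 4621 genes up and 4830 down. Median scaling on the probes detected on all 12 arrays, added after the data were seen, moved it to 0.36 and gave 5869 up and 3528 down. List medians of a line, and those of the differences between lines, are therefore given here relative to the median of all genes in the same comparison. Of the 5663 genes that fell, 1691 were not above background on either treated array.

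Immediate early genes, which encode AP-1, EGR and related rapid-response factors, rose as a group in MM.1S. Of 19 measured members 16 rose, 2 fell and 1 did not pass, with a median 2.16 log2 units above that of all genes (camera adjusted p = 2e-07). IER3, an early response gene linked to cell survival, rose by 5.51 ± 0.14 log2 units, FOS was at least 12-fold and EGR1 at least 17.1-fold higher. DDIT4 and DDIT3, which are induced by the integrated stress response, rose by 3.70 ± 0.07 and 2.80 ± 0.07 log2 units, and the ATF4 list they belong to had 8 members up and 13 down of 26 (camera adjusted p = 0.51). The inhibitor of NF-kB NFKBIA rose by 3.24 ± 0.09 and NFKB2 by 1.52 ± 0.07, with 7 of 17 NF-kB targets up and 4 down (adjusted p = 0.223). HRK, a BH3-only member of the BCL2 family, rose by 2.39 ± 0.12.

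Genes of cell division and protein turnover were lower relative to all genes in treated MM.1S. None of 25 mitotic genes rose and 21 fell (22 adjusted over the list alone), among them the spindle genes HMMR, by 1.20 ± 0.12 log2 units, and TPX2, by 1.16 ± 0.09. The list median lay at -0.32 (camera adjusted p = 0.00762; adjusted p = 0.0798 with an estimated correlation). Of 23 DNA replication genes 17 fell and 2 rose, led by RRM2, a subunit of ribonucleotide reductase, with -1.57 ± 0.10, and SLBP, which binds histone mRNA, with -1.42 ± 0.08. Their median of -0.26 had a camera adjusted p of 0.0493 (adjusted p = 0.166 with an estimated correlation), and the call ended without control replicate 2 (0.0583) or either treated replicate (0.0813). Among 27 proteasome subunits 23 fell (24 adjusted over the list alone) and 2 rose, with PSMB2 at -1.16 ± 0.08 (camera adjusted p = 0.0115; adjusted p = 0.108 with an estimated correlation). All but 1 of 13 housekeeping genes fell, with a median of -0.58 (camera adjusted p = 0.01; adjusted p = 0.214 with an estimated correlation), including the cyclophilin PPIA, at least 1.72-fold. Under all 5 ways of scaling and background handling these lists kept their direction relative to all genes.

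The remaining lists did not pass in MM.1S, although without the detection filter NRF2 targets (camera adjusted p = 0.00729), unfolded protein response genes (0.00474), plasma cell genes (0.00729) and sterol synthesis genes (0.0194) did, as did unfolded protein response and sterol genes under scaling on the probes detected on all arrays (both 0.0241). Of 22 measured p53 targets 4 rose and 15 fell (camera adjusted p = 0.583). CDKN1A counted among the falls on its brightest probe, while its other probe gave 5.08 log2 units. No list was tested with the mean of all kept probes of a gene. ZMAT3, an RNA-binding p53 target, rose by 2.37 ± 0.08 log2 units on its brightest probe, while its other 2 probes gave -1.49 and -1.61; PPM1D, a phosphatase acting on p53, was at least 2.94-fold lower. NRF2 targets had 1 member up and 15 down of 19 (0.0623), including TXNRD1 with -1.43 ± 0.08 and NQO1 with -1.40 ± 0.15. Heat shock genes had 7 up and 10 down of 23 (0.186), ER chaperone and unfolded protein response genes 2 up and 16 down of 21 (0.1), and metallothioneins 2 up, MT1X and MT2A, and 2 down of 8 (0.381). The MYC and ribosome list had 9 up and 10 down of 22 (0.51), plasma cell genes 3 up and 11 down of 16 (0.126), glutathione and thioredoxin genes 2 up and 10 down of 20 (0.566), sterol synthesis genes 2 up and 12 down of 14 (0.131), interferon response genes 4 up and 6 down of 18 (0.705), autophagy genes 3 up and 12 down of 18 (0.275) and the BCL2 family 4 up and 8 down of 15 (5 and 8 adjusted over the list alone; 0.838). Before subtraction of the all-gene median, the signs of median, mean and test differed in MM.1S for the heat shock, ATF4, BCL2, metallothionein, MYC and ribosome, NF-kB and interferon lists, in U266 for sterol genes, and in 8226R5 for p53 targets and immediate early, glutathione, proteasome, sterol and other cell type genes, none of which passed. After it, the median had the opposite sign to the test for glutathione genes in MM.1S (0.09) and, in 8226R5, for immediate early, glutathione, proteasome, sterol, interferon and other cell type genes. Scaling turned the sign of the unsubtracted median change in MM.1S of the p53, heat shock, ATF4, BCL2, metallothionein, NF-kB, glutathione and interferon lists.

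Markers of other cell types did not pass as a list in MM.1S, where 3 rose and 1 fell of 12 (camera adjusted p = 0.0623), in U266 (4 and 1; 0.068) or in 8226R5 (2 and 0; 0.705). In MM.1S 11 rose and none fell under both median scalings, and the list passed with the authors' values (0.046), with the replicate number as a block (0.0447), without control replicate 2 (0.0408) and under scaling on the probes detected on all arrays (0.00585). In U266 it passed under that scaling (0.00181, with 9 up), without control replicate 1 (0.0446) and without treated replicate 1 (0.0183). The liver transcript ALB rose by 5.36 ± 0.12 log2 units and FCGR3A, an Fc receptor of natural killer cells and monocytes, was at least 12.8-fold higher. In U266 ALB rose by 3.09 ± 0.12, and in 8226R5 by 0.58 ± 0.12. CD14, a monocyte receptor, was at least 2.69-fold higher in U266.

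In U266, metallothioneins, small cysteine-rich proteins that bind zinc and copper, gave the largest rises. MT1G was at least 135-fold higher after treatment (limma adjusted p = 1.82e-10, n = 2 per group), MT1H at least 28.4-fold, and MT2A rose by 5.27 ± 0.07 log2 units (SE). EGR1 was at least 29.2-fold higher, and the small nuclear RNA RNVU1-7 rose by 4.53 ± 0.11. The largest fitted falls were in TRIB1, a pseudokinase, with -2.69 ± 0.08, RASD1, a small GTPase, with -2.58 ± 0.16, the chemokine receptor CCR2 with -2.50 ± 0.16, RUNX2, a transcription factor (at least 2.72-fold), and LOC730101 (at least 3.83-fold). The last 2 were not above background after treatment, so their rank is not established, and another probe of RUNX2 gave 0.02 in U266.

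The test called 3366 genes (29.8%) in U266, 1507 up and 1859 down, and 434 genes differed by at least 2-fold, 181 up and 253 down. That number was 274 with the authors' values, 283 without background correction and 242 with an offset of 50. Median scaling gave 3473 up and 1669 down, and scaling on the probes detected on all arrays gave 3328 up and 1761 down. The count was 2008 without control replicate 1 and 2035 without control replicate 2.

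Of 8 measured metallothionein and metal response genes 7 rose and 1, the zinc exporter SLC30A1 (chosen after its value was seen), fell in U266, with a median 4.15 log2 units above all genes (camera adjusted p = 1.44e-08). Of 23 heat shock genes 14 rose and 1 fell (median 0.43, adjusted p = 3.63e-06), with HSPA1B at 3.02 ± 0.10 and HSPA6 at least 4.56-fold higher, although another probe of HSPA6 gave 0.23. Among immediate early genes 8 rose and 3 fell of 19 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00559, adjusted p = 0.0798 with an estimated correlation), and FOS was at least 6.79-fold higher. In the ATF4 list 11 rose and 5 fell of 26, including DDIT4 with 1.32 ± 0.07 and DDIT3 with 1.23 ± 0.07 (camera adjusted p = 0.0185; adjusted p = 0.206 with an estimated correlation). Interferon response genes fell, 10 of 18 with 1 up (11 and 1 adjusted over the list alone), among them IFI44L with -1.15 ± 0.07 and IFIT1 with -1.14 ± 0.33 (camera adjusted p = 0.00259; adjusted p = 0.0798 with an estimated correlation). Plasma cell genes fell, 7 of 16 with 2 up (7 and 3 adjusted over the list alone), led by IRF4, a transcription factor on which myeloma cells depend, with -1.65 ± 0.11, and ELL2, an elongation factor for immunoglobulin secretion, with -1.32 ± 0.08 (camera adjusted p = 0.00998; adjusted p = 0.102 with an estimated correlation).

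DNA replication genes fell relative to all genes in U266, 9 of 23 with 1 up (10 and 1 adjusted over the list alone), including RRM2 with -1.33 ± 0.10 and MCM4, a subunit of the replicative helicase, with -0.84 ± 0.08 (camera adjusted p = 0.00559; adjusted p = 0.0798 with an estimated correlation). That call and the plasma cell call ended under scaling on the probes detected on all arrays (adjusted p = 0.188 and 0.0583), and median scaling moved the median change of replication genes from -0.22 to 0.01. The other 13 lists did not pass (camera adjusted p 0.0671 to 0.868), although NF-kB targets, with 3 up and 7 down of 17, did with the authors' values (0.0482) and without the detection filter (0.0119). Among them p53 targets had 2 up and 6 down of 22 (0.343), with TP53INP1 at -1.35 ± 0.10 and the cytokine GDF15 at 0.90 ± 0.12, and NRF2 targets 2 up and 5 down of 19 (0.705). MYC was at least 1.7-fold lower, IL6, a growth factor of myeloma cells, changed by -1.94 ± 0.09, and the anti-apoptotic BCL2L1 by -0.98 ± 0.08.

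In 8226R5, heat shock genes and NRF2 targets rose and NF-kB targets fell. HSPA1B rose by 2.94 ± 0.10 log2 units (SE, n = 2 per group), its co-chaperone DNAJB1 by 2.41 ± 0.06, EGR1 by 2.99 ± 0.07 and FOS by 2.93 ± 0.18, and HSPA6 was at least 3.73-fold higher, or 0.97 log2 units on another probe (limma adjusted p 3.5e-07 to 5.61e-05). The largest fitted falls were those of the cytokine OSM with -2.36 ± 0.25, DEPP1, a FOXO target, with -2.02 ± 0.15, TRIB1 with -1.85 ± 0.08, the phosphodiesterase PDE4B (at least 1.68-fold) and the stress gene GADD45G (at least 2.89-fold); for the last 2, not above background after treatment, the rank is not established.

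Of the tested genes 1415 (12.5%) changed in 8226R5, 602 up and 813 down, and 124 differed by at least 2-fold, 58 up and 66 down. For the latter the authors' values gave 65, no background correction 72 and an offset of 50 gave 60. The calls numbered 2353 under scaling on the probes detected on all arrays, 721 up and 1632 down, and 528 to 629 when any of the 4 arrays of this line was left out.

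Heat shock genes had 9 of 23 members up and none down in 8226R5 (11 and none adjusted over the list alone; median 0.32, camera adjusted p = 9.42e-09). NRF2 targets, genes of antioxidant defence, had 7 of 19 up and none down (9 and none adjusted over the list alone; median 0.36, adjusted p = 4.56e-06), including SRXN1, which repairs oxidised peroxiredoxins, with 0.90 ± 0.10 and the pentose phosphate enzyme TKT with 0.60 ± 0.08. NF-kB targets had 7 of 17 down and none up (8 and none adjusted over the list alone; median -0.18, adjusted p = 0.000189), with the deubiquitinase TNFAIP3 at -1.27 ± 0.07 and NFKBIA at -1.09 ± 0.09. Metallothioneins had 3 of 8 up, among them MT1X with 0.89 ± 0.09 (camera adjusted p = 0.0104; adjusted p = 0.102 with an estimated correlation). The ATF4 list had 4 of 26 up, with ATF3 at 0.78 ± 0.10 (camera adjusted p = 0.0115; adjusted p = 0.189 with an estimated correlation, 0.053 without control replicate 2 and 0.0501 without treated replicate 2). Mitotic genes had 4 up and 1 down of 25, with TPX2 at 0.45 ± 0.09 and CENPF at -0.47 ± 0.11 (camera adjusted p = 0.0185; adjusted p = 0.102 with an estimated correlation). Plasma cell genes had 3 of 16 down, with none up (4 and none adjusted over the list alone), led by PRDM1, the master regulator of plasma cells, with -1.78 ± 0.10 (camera adjusted p = 0.0234; adjusted p = 0.151 with an estimated correlation, 0.0734 without control replicate 1 and 0.0633 without treated replicate 1). Autophagy genes, with 3 of 18 up (0.068), passed without the detection filter (0.0266), under scaling on the probes detected on all arrays (0.029) and without treated replicate 2 (0.0441). They were among the other 13 lists that did not pass (camera adjusted p 0.068 to 0.868), as were p53 targets with 1 up, BAX at 0.85 ± 0.12, and 1 down, SESN1 at -0.59 ± 0.07, of 22 (0.868).

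**Figure D2:**
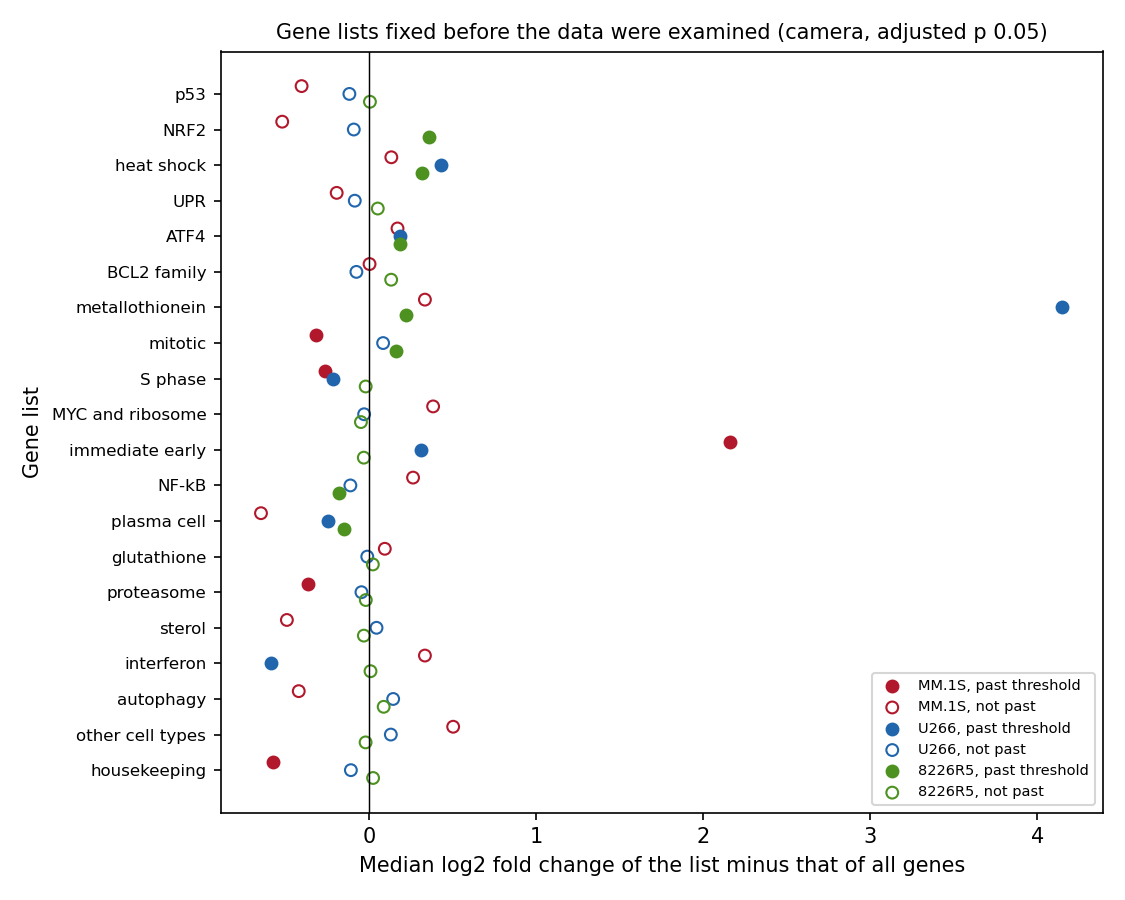
Median log2 fold change of each of the 20 gene lists minus the median of all genes, for the 3 lines; filled points passed a camera adjusted p of 0.05 and open points did not. Metallothioneins in U266 (4.15) and immediate early genes in MM.1S (2.16) lie farthest from 0; the U266 replication genes (-0.21) kept a negative value relative to all genes under every scaling, while their own median change turned from -0.22 to 0.01 under median scaling.

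Of the 60 list tests over the 3 lines 19 passed with camera's preset correlation, and 6 of them passed with an estimated correlation, namely immediate early genes in MM.1S, metallothioneins and heat shock genes in U266, and heat shock genes, NRF2 targets and NF-kB targets in 8226R5.

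Genes fixed in advance for every line included targets often measured with this drug. PMAIP1, which encodes the BH3-only protein NOXA, was detected on the 4 8226R5 arrays alone and differed there by 0.11 ± 0.10 log2 units (limma adjusted p = 0.51). CDKN1A, the cell cycle inhibitor p21, fell by 0.60 ± 0.11 in MM.1S (adjusted p = 0.000761) on its brightest probe, whereas a dimmer probe detected on 3 arrays gave 5.08. In U266 and 8226R5 the brightest probe gave -0.16 ± 0.11 and -0.30 ± 0.11 (adjusted p = 0.308 and 0.112), and the dimmer probe gave 1.05 and -0.03. MDM2, the ubiquitin ligase of p53, lay near background and did not pass in MM.1S, U266 or 8226R5 (adjusted p = 0.567, 0.903 and 0.0942). The haem oxygenase HMOX1 was not above background in treated MM.1S, where its lower value (adjusted p = 0.0201) turned to 0.41 and 0.81 under both median scalings, and it did not pass in U266 or 8226R5 (0.0972 and 0.0553). The probe of TP73 was not detected on any array, and 1 of the 6 fixed genes had no probe in the annotation used here.

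**Figure D3:**
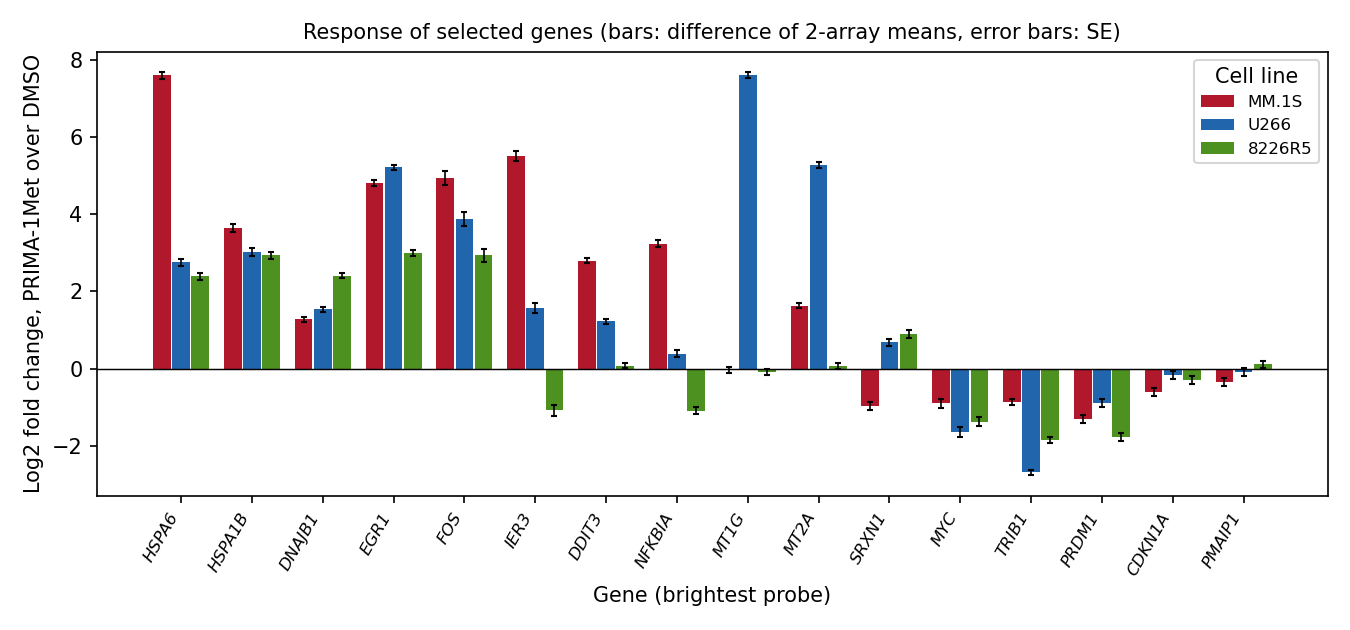
Log2 fold change of 16 genes in the 3 lines, as differences of 2-array means with the SE as error bars. HSPA6, HSPA1B, DNAJB1, EGR1 and FOS lie above 0 and MYC, TRIB1 and PRDM1 below 0 in every line, while MT1G, at least 135-fold higher in U266, stands out in that line alone; PMAIP1 was below background in MM.1S and U266 and its sign there turned under median scaling (0.93 and 0.58), other probes of CDKN1A (5.08) and PRDM1 (1.06) went the other way in MM.1S, and bars with an undetected group, such as HSPA6 in MM.1S, are fitted values and not bounds.

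Averaged over the lines, the largest fitted rises were those of EGR1, HSPA6, FOS and the small nuclear RNAs RNU4-2 and RNU6ATAC (limma adjusted p 1.22e-10 to 1.43e-08). RNU4-2, detected in all groups, rose by 3.97 ± 0.04 log2 units; the others were undetected in the controls of at least 2 lines, so no mean is given for them. Among the largest fitted falls with one sign in all lines, TRIB1 fell by 1.80 ± 0.04 and RUNDC1 by 1.46 ± 0.20. RUNX2 and ZNF17, also among them, had groups that were not above background, and the other probe of RUNX2 gave 0.02 in U266 and 0.10 in 8226R5. The 3-line mean differed from 0 for 7331 genes, 2321 up and 5010 down (limma adjusted p under 0.05). Median scaling gave 3998 up and 4187 down, scaling on the probes detected on all arrays 5011 up and 3042 down, and a fit without the MM.1S arrays, added after the data were seen, called 3187 genes.

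Metallothioneins had 7 members up and 1 down of 8 in the 3-line mean, immediate early genes 14 up and 4 down of 19, and heat shock genes 12 up and 2 down of 23, with camera adjusted p of 2.76e-05, 1.49e-05 and 0.000137. These 3 lists also passed with an estimated correlation. A further 6 lists passed with the preset correlation alone: replication genes with 18 of 23 down (adjusted p = 0.0103; 0.105 with an estimated correlation), plasma cell genes with 11 of 16 down (12 adjusted over the list alone; 0.0103; 0.108), housekeeping genes with 12 of 13 down (0.0103; 0.232), proteasome subunits with 20 of 27 down (0.0372; 0.171), markers of other cell types with 4 of 12 up (0.0372; 0.171) and the ATF4 list with 11 up and 10 down of 26 (0.0498; 0.282).

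The changes were shared to a different degree in each pair of lines. Of the genes called in both lines, 73.1% went the same way in MM.1S and U266. The share was 47.9% in MM.1S and 8226R5 and 58.8% in U266 and 8226R5. MM.1S and U266 had 771 genes up in both lines, where independent lists would share 361.1, and 1222 down in both against 931.2, while 733 went opposite ways against 1200. MM.1S and 8226R5 shared 201 rises (144.3 by independence) and 323 falls (407.3), with 569 in opposite directions (496.4). For U266 and 8226R5 the numbers were 150 (80.25), 252 (133.7) and 282 (207.4). Fold changes correlated across genes, which are not independent replicates, at r = 0.376, 0.0225 and 0.115 for the 3 pairs. In all 3 lines 87 genes rose and 134 fell, where independence would give 19.23 and 66.97. Many of these shared rises were small non-coding RNAs, such as RNU4-2, RN7SK and SNORD17, and some were replication-dependent histones, such as H4C1. The overlaps were counted under the main scaling alone. The MM.1S calls they use moved from 2709 up and 5663 down to 5869 and 3528 under scaling on the probes detected on all arrays.

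The response differed between lines for 8220 genes (72.7%) by limma's F test of the interaction. MM.1S differed from U266 at 7308 genes and from 8226R5 at 7547, and U266 from 8226R5 at 2552. The first of these had 2553 genes with the higher change in MM.1S and 4755 with the lower, but 3702 and 4523 under median scaling and 5157 and 3104 under scaling on the probes detected on all arrays. Against 8226R5 the split was 2641 and 4906, then 4440 and 4319, then 5694 and 2930. For U266 minus 8226R5 it was 1258 and 1294, then 3002 and 1176, then 3150 and 1151. RASD1 gave the largest positive difference between MM.1S and U266, since it was at least 17.7-fold higher in treated MM.1S and fell by 2.58 ± 0.16 log2 units in U266. MT1G gave the largest negative difference and also the largest between U266 and 8226R5, being at least 135-fold higher in treated U266 and not past the threshold in the other lines. IER3 rose by 5.51 ± 0.14 in MM.1S and fell by 1.08 ± 0.14 in 8226R5, and NFKBIA rose by 3.24 ± 0.09 in MM.1S and fell by 1.09 ± 0.09 in 8226R5. JAK1, at least 3.94-fold lower in MM.1S, rose by 0.71 ± 0.14 in 8226R5. MCL1, an anti-apoptotic BCL2 relative, rose by 1.27 ± 0.08 in 8226R5 and fell by 0.85 ± 0.08 in MM.1S and 0.91 ± 0.08 in U266, but another of its probes gave 1.26 in MM.1S.

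By camera on the differences, immediate early genes responded more in MM.1S than in U266 (median difference 1.36, adjusted p = 5.68e-05) and than in 8226R5 (2.16, adjusted p = 3.36e-06), and metallothioneins more in U266 than in 8226R5 (3.56, adjusted p = 2.86e-06). These calls held with an estimated correlation. The change of NRF2 targets was lower in MM.1S, where most members fell, than in 8226R5, where none fell (-0.77, adjusted p = 0.00713, or 0.116 with an estimated correlation). It was also lower in U266 than in 8226R5 (-0.40, adjusted p = 0.00292, or 0.107 with an estimated correlation).

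Before treatment, p53 targets did not stand apart in the line labelled p53 wild type. Against the mean of the U266 and 8226R5 controls, 7 of 22 were higher in MM.1S controls, 6 lower and 9 not past the threshold, with a median difference of 0.08 log2 units (camera adjusted p = 0.703). With 1 line per p53 status, this compares these lines.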

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

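The tests on the size of the MM.1S response that concern quantile normalization, loss near background and dose, and all tests on histones and metallothioneins, were chosen after the results were seen, while the test on a smaller amount of messenger RNA was written before its result was seen.

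Responses that differed between lines by a test of the difference itself are listed here. The F test called 8220 genes, and pairwise tests called 7308 genes between MM.1S and U266, 7547 between MM.1S and 8226R5 and 2552 between U266 and 8226R5. Of the 122 measured named genes 114 passed the F test, 36 changed in opposite directions in a pair of lines, and 6 did so by at least 2-fold in both. Most of these genes were named for large changes or differences in the same data, so the shares do not measure how common such differences are.

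Fitted differences on the log2 scale follow, which are not bounds where a group was undetected. For MM.1S minus U266 they were 7.504 for RASD1, 6.077 for H2AC6, 6.015 for H4C8, -7.655 for MT1G, -5.949 for MT1H and -4.512 for MT1E (limma adjusted p 3.53e-09 to 1.52e-05). For MM.1S minus 8226R5 they were 6.752 for the probe of MIR425, 6.648 for LOC105274304, 6.596 for IER3, 4.329 for NFKBIA and 3.218 for GADD45G, which was undetected in MM.1S, and -4.586 for JAK1, -3.759 for the probe of MIR1228 and -3.738 for NOMO3 (1.47e-08 to 1.73e-06). For U266 minus 8226R5 they were 7.702 for MT1G, 5.197 for MT2A, 5.109 for MT1H, -3.581 for RASD1, -2.876 for VOPP1 and -2.743 for XPOT (3.35e-09 to 0.000326).

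Lists whose response differed between lines are given by the median of the difference, with the camera adjusted p; these medians are not relative to all genes, whose median lay at -0.301 for MM.1S minus U266, -0.313 for MM.1S minus 8226R5 and 0.0246 for U266 minus 8226R5. Between MM.1S and U266 it was -2.85 for metallothioneins (0.00292), -0.818 for mitotic genes (0.00292), 1.06 for immediate early genes (5.68e-05), 0.477 for NF-kB targets (0.0194), -0.688 for proteasome subunits (0.0137) and -1.03 for housekeeping genes (0.0154). Between MM.1S and 8226R5 it was -1.08 for NRF2 targets (0.00713), -0.832 for mitotic genes (0.00292), 1.85 for immediate early genes (3.36e-06), 0.858 for NF-kB targets (0.0137), -0.789 for proteasome subunits (0.0084) and -0.881 for housekeeping genes (0.00713). Between U266 and 8226R5 it was -0.372 for NRF2 targets (0.00292), 3.59 for metallothioneins (2.86e-06), 0.349 for immediate early genes (0.0446) and -0.4 for interferon response genes (0.0101). With an estimated correlation the calls that held were immediate early genes in both comparisons with MM.1S (adjusted p = 0.045 and 0.0396) and metallothioneins between U266 and 8226R5 (0.0396).

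MM.1S responded at more genes than the other lines, on treated arrays that were dim. Quantile normalization is argued against as the whole cause, since median scaling gave 5030 genes at least 2-fold changed in MM.1S and 493 in U266. Loss near background is argued against likewise, since in the highest of 3 equal groups of genes by mean expression 30.4% changed at least 2-fold in MM.1S and 2.63% in U266. A smaller amount of messenger RNA that moved all messages alike is argued against by the SD of the log2 changes among protein-coding genes of that group, 0.969 in MM.1S and 0.381 in U266. That test addresses a uniform loss alone, so an unequal loss of messages was not tested and stays open. Among genes with several probes, 9.19% had probes over 2 log2 units apart in MM.1S, 0.106% in U266 and 0% in 8226R5. An effect of the cell line, its p53 status or its dose may also underlie the difference. Line, status and dose cannot be told apart, since 1 line was treated at the dose of MM.1S.

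Replication-dependent histone transcripts such as H2AC6 and H4C8 rose in MM.1S, and most such messages lack a poly(A) tail. A loss of messenger RNA that lifted all transcripts without a tail alike is argued against, since small nuclear RNAs detected on all MM.1S arrays had a median change of 5.25 (quartiles 4.23 to 5.82) and small nucleolar RNAs one of 2.43 (1.26 to 3.08). Replication genes, whose median lay at -0.262 relative to all genes, gave no sign of a gain of S phase cells. An unequal loss of messages, left open above, could lower these genes too, so this test cannot decide the question. A lift of short genes is argued against by a median of 3.62 for histones. The other protein-coding genes in the shortest of 10 equal groups by length had 0.0943. The 8 histones detected on all MM.1S arrays had a median of 2.03 (quartiles 0.509 to 3.43), so the size of the rise is uncertain, and an unequal lift of transcripts without a tail stays open and may contribute.

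Metallothioneins rose in U266 far more than in 8226R5 at the same dose. Metal in the drug solution that acted alike on every line is argued against for MT1E, MT1G and MT1H. These members, chosen for a low control level in 8226R5, had a median change of 0.22 in 8226R5 and 6.02 in U266. In MM.1S, MT1X and MT2A rose by 2.30 and 1.64, while MT1E, MT1F, MT1G and MT1H changed by -0.59 to 0.07. MT1X and MT2A, high in the 8226R5 controls, changed by 0.89 and 0.07 in 8226R5 and by 4.37 and 5.27 in U266. A metal effect that differed in size between lines was not tested. Members chosen for a low level in 8226R5 may be unable to respond there, so an equal exposure to metal stays open. The transcript of MT1X or MT2A read by the probes of MT1E, MT1G and MT1H is argued against by their levels relative to MT1X or MT2A, which were higher in treated U266 than in 8226R5 controls by at least 4.27 log2 units under 5 ways of scaling and background handling. The transcript of MT1G read by the probes of the other paralogs cannot be told apart from a rise of each, since MT1G changed past the threshold in 1 line, U266. A difference in zinc handling between the lines, or in p53 status, may underlie the rise and was not tested.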

How the results depend on the processing

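The alternatives of scaling on probes detected on all arrays, deposited positions without realignment, leaving out the MM.1S arrays and genes detected on all arrays were chosen after the data were seen, and the others before. The cause of a change was not tested unless stated.

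With the authors' values, 274 genes in U266 and 65 in 8226R5 differed by at least 2-fold, and fold changes correlated across genes at 0.388 for MM.1S and U266 and 0.0317 for MM.1S and 8226R5. Without background correction these values were 283, 72, 0.384 and 0.0302, and an offset of 50 gave 242 and 60 genes. Without a detection filter the 3 correlations were 0.365, 0.0150 and 0.0898. Median scaling gave 5142 genes in U266, 2141 in 8226R5 and 4178 between them, and scaling on probes detected on all arrays gave 5089, 2353 and 4301. Of the 8372 MM.1S calls, median scaling kept 6798 in the same direction and turned 517, and scaling on probes detected on all arrays kept 6226 and turned 961.

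Under those scalings PMAIP1 turned to 0.93 and 1.33 in MM.1S and to 0.58 and 0.57 in U266, and HMOX1 in MM.1S to 0.41 and 0.81. With the mean of all kept probes ZMAT3 in MM.1S turned to -0.24 and CDKN1A to 2.24 in MM.1S and 0.44 in U266, because their probes differed. Of 151 results for named genes 150 kept direction and side of the threshold with the authors' values, 144 under median scaling and 142 each under scaling on probes detected on all arrays, with the mean of probes and with the replicate block, which put 7 no longer past the threshold. Leaving out 1 array kept 524, put 79 no longer past it and 1 newly past it.

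A threshold of adjusted p and 2-fold together left, by its construction, 4119 genes in MM.1S, 433 in U266, 122 in 8226R5, 500 in the 3-line mean, and 3771, 4357 and 638 for MM.1S minus U266, MM.1S minus 8226R5 and U266 minus 8226R5. Restriction to genes detected on all arrays left 5079 calls in MM.1S among 5966 tested. Without the MM.1S arrays the mean over lines called 3187 genes.

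The deposited positions without realignment gave 1277 genes in U266, 297 in 8226R5, 4330 in the 3-line mean, 4424, 4578 and 765 in the pairwise comparisons in the same order, 4973 by the F test and 6285 at least 2-fold in MM.1S.

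Of the 60 list tests, 6 passed with an estimated correlation and 49 with fry, which does not compare a list with other genes. Fry turned the direction of the BCL2, MYC and ribosome and interferon lists in MM.1S, whose members went both ways. Before subtraction of the all-gene median their medians were -0.349, 0.0313 and -0.0179. The baseline p53 list (median 0.0799) passed with limma's fry (adjusted p = 2.64e-06) and not with camera (adjusted p = 0.703).

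With the replicate number as a block (paired fit), 728 genes were called in 8226R5 (313 up and 415 down), 8239 in MM.1S, 2589 in U266 and 7092 in the 3-line mean, and 19 list tests passed; replication genes in MM.1S lost their call (adjusted p = 0.0564). No pairing by replicate number was visible, since treated and control replicate differences correlated across genes at 0.0114, -0.0112 and -0.00633 in MM.1S, U266 and 8226R5. These values cannot show whether the samples were prepared in pairs. Chip as a block was not run, since the files give no chip.

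Leaving out 1 array gave 7681 to 8393 genes in MM.1S, 2008 to 2431 in U266, 528 to 629 in 8226R5, 6843 to 7743 in the 3-line mean, 6628 to 7630, 6963 to 7858 and 1688 to 2124 in the pairwise comparisons, and 7622 to 8693 by the F test; the lone array is assumed to vary like the other groups. Genes at least 2-fold changed numbered 4152 to 4247, 432 to 500 and 136 to 146 in the 3 lines, list tests passed 17 to 20 times, and the baseline p53 median was 0.0499 to 0.113. Arrays whose removal moved a count by over 1.5 times were, in 8226R5, control 1 (606), control 2 (629), treated 1 (528) and treated 2 (568), and in U266 control 1 (2008) and control 2 (2035). For U266 minus 8226R5 they were U266 control 1 (1688), U266 control 2 (1688) and 8226R5 treated 2 (1699).

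A stricter detection filter, a trended and robust prior, and a fit on the 4 arrays of a line kept each count within 1.5 times. Signal over background limited the treated MM.1S arrays, where 1691 of the genes that fell were undetected.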

Other observations

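The test of other splits and the test of gene length were written before their results were seen, and the choice to look at RNA classes and at baseline lists other than p53 targets was made after.

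Small nuclear RNAs, the RNA parts of the spliceosome, had more members up than down in all 3 lines, with the largest median change where treated arrays were dimmest. The 90th percentile of signal went from 812.5 to 213.7 intensity units in MM.1S, from 905.3 to 535.4 in U266 and from 700.9 to 867.2 in 8226R5. Of 14 measured, 13 rose in MM.1S (median log2 change 5.34, camera adjusted p = 1.2e-11), 13 in U266 (3.03, 5.09e-19) and 7 in 8226R5, with 1 down (0.63, 2.98e-07). Small nucleolar RNAs, which guide the modification of ribosomal RNA, had 115 of 128 up and 4 down in MM.1S (2.40), 35 up and 8 down in U266 (0.18) and 32 up and 10 down in 8226R5 (0.25). Replication-dependent histones had 52 of 54 up in MM.1S (3.62), 12 up and 4 down in U266 (0.13) and 8 up in 8226R5, where the median of 0.11 turned to -0.0447 and -0.074 under both median scalings. Among histones detected on all arrays of a line the median was 2.03 in MM.1S (8 members), -0.138 in U266 (22) and -0.135 in 8226R5 (14), so the sign of the U266 and 8226R5 medians turned. Long non-coding RNAs had 85 of 219 up and 43 down in MM.1S (164 and 22, and 186 and 11, under the median scalings), 33 up and 27 down in U266 and 5 up and 21 down in 8226R5, and passed as a class in MM.1S alone (camera adjusted p = 7.76e-07, 0.323 and 0.225). All these calls for small RNAs and histones held with an estimated correlation.

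Before treatment, lists set MM.1S apart from the mean of the other controls. Plasma cell genes had 14 of 16 higher and 2 lower in MM.1S (median difference 2.62, camera adjusted p = 1.15e-06) and ER chaperone and unfolded protein response genes 18 of 21 higher (0.994, 4.46e-06). Mitotic genes had 18 of 25 higher (0.39, 0.00219). Interferon response genes were lower at 18 of 18 (-3.1, 8.1e-10), and ATF4 and amino acid response genes at 22 of 26 (-1.25, 1.15e-06). These 5 lists passed with an estimated correlation, whereas sterol synthesis genes (0.593, 0.0225) and markers of other cell types (-0.875, 0.0225) did not (adjusted p = 0.1 and 0.135).

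Longer genes had lower values in treated MM.1S. Across 10606 protein-coding genes, which are not independent replicates, the Spearman correlation of change with gene length was -0.256 in MM.1S, -0.0522 in U266 and 0.0877 in 8226R5. A relation to gene length apart from mean expression may contribute, since the weakest of 3 equal groups by mean expression had -0.199 and the others -0.305 and -0.279. Median changes ran from 0.0943 in the shortest of 10 equal groups by length to -0.683 in the longest.

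Probes of a gene differed more in MM.1S, where 261 of 2841 genes (9.19%) had probes whose changes differed by over 2 log2 units, against 3 in U266 and 0 in 8226R5.

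For the 3-line mean a random grouping of these arrays is argued against as the source of the count. Of 100 splits drawn from 108 within the lines, 1, the real one, gave as many genes. The real split called 7331 genes and the highest other 7293. That other split kept the groups of each line and turned the direction of a line, and the highest that mixed treated and control arrays called 6377. Since turning a line changed the count little, the count does not measure a response shared by the lines. Chance between cultures cannot be judged from the splits, since the labels do not say that the samples of a group were separate cultures.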
